A study of Mus musculus with 12 samples.

How the data were processed

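Transcripts were measured in T cells of 5CC7 mice, whose transgenic T cell receptor recognises a moth cytochrome c peptide. Per the labels, such cells were transferred into B10.A mice, which then received 2 µg or 0.2 µg of a peptide into the tail vein. The peptide was MCC, named in the labels as the strong agonist of this receptor, or 102S, named as the weak one. The lymph nodes were pooled 48 h after the injection and the transferred cells were sorted by flow cytometry. Total RNA was extracted with Trizol, and 100 ng was biotin-labelled with a 3′ in vitro transcription kit, the transcription step lasting 16 h, per the labels' protocols. Each of the 4 combinations of peptide and dose had 3 arrays, 12 in all. No unstimulated cells were analysed here.

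The deposited table held 1 log2 expression value per probe set and array for 22690 probe sets of an Affymetrix mouse array. The scale was read from the values, which lay between 1.86 and 14.7 with array medians near 5.2. The software GCOS 1.4 is named in the submitters' processing notes. How the authors summarised probes into log2 values, corrected the background and scaled the arrays is not given in the sources used here. The array medians differed by at most 0.089 log2, below the limit of 0.15 log2 above which quantile normalization would have become the main setting, so the log2 values were used as deposited. Arrays carry no read depth. Their number limits the precision, and a median standard error of 0.18 log2 applied to a difference between groups of 3.

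Gene names came from the platform annotation supplied with the table. Of the 22690 probe sets, 20393 had 1 gene symbol, 691 had several and 1606 had none, and 64 were Affymetrix controls. Entrez identifiers of 20364 probe sets were found in a RefSeq gene table of the assembly GRCm38.p6, which was used for names and chromosomes only and changed 0 symbols. No gene was named from a probe set with several symbols. Control probe sets, and probe sets whose mean over the 12 arrays lay under the 40th percentile (log2 4.48), were left out of the tests. This left 13556 probe sets, 12423 of them with 1 symbol, for 7945 genes. Where a gene had several probe sets, the one with the highest mean stood for it. No named gene that was called had another tested probe set called in the opposite direction in the same comparison. Genes that were not named were not checked for this.

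The log2 values were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intensity trend, 4 group means and no further covariate. All 12 arrays shared one estimate of the spread per probe set, with 8 residual and 4.16 prior degrees of freedom. The tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg over the 13556 probe sets of a comparison, with a threshold of 0.05. The comparisons were MCC against 102S at each dose, 2 µg against 0.2 µg of each peptide, the interaction of peptide and dose, and 0.2 µg of MCC against 2 µg of 102S. The interaction is the MCC minus 102S difference at 2 µg minus that at 0.2 µg. The ± values given with differences are standard errors of this fit, and those given with group means are standard deviations over 3 arrays. The labels do not state that replicates were separate animals or cultures, so the p-values measure only the spread between these samples. Sex-linked transcripts, given below, show cells of another source in replicate 1, so that spread is not technical alone. Replicates 2 and 3 may still share a source, and their spread may be technical.

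Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with a correlation estimated for each list, and fry, were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. There were 31 lists, covering the cell cycle, activation, helper subsets, metabolism, stress, sex-linked genes and markers of other cell types that a sort could retain. The 27 lists with at least 5 measured genes were tested. The groups, comparisons, filter, lists, the 22 key genes named whatever their result, and the rule for other named genes were fixed before the data were examined. That rule took, in each comparison, the 10 highest and 10 lowest differences among called genes whose groups did not overlap, and up to 4 genes of each list by smallest p. For the interaction the overlap was not considered. Key genes with no probe set of their own in the annotation were not analysed here. Peptide and dose effects were also correlated across probe sets.

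The fit was tested on simulated arrays with 13556 probe sets, of which 100 were changed by 1 log2 and 100 by 2 log2. It recovered 71% and 98% of these for MCC against 102S at 2 µg, with 7 false calls. For the dose of MCC it recovered 72% and 96%, with 11 false calls, and for the interaction 47% and 86%, with 6 false calls. With camera, 0 of 50 unchanged lists were called, and a list of 20 genes with 10 raised was called, in the setting of MCC against 102S at 2 µg. The simulated values were drawn independently for each probe set and array, without correlation between genes or a shared structure of arrays. These counts therefore do not measure the error rates of the real arrays and lists.

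Labels give every group replicates numbered 1 to 3 and do not say what a number shares. Arrays were taken as paired where the deviations of all 3 same-numbered pairs from their group means correlated above 0.1. This was met for MCC against 102S at 2 µg (0.601, 0.195 and 0.241), for the dose of MCC (0.562, 0.203 and 0.217) and for 0.2 µg of MCC against 2 µg of 102S (0.822, 0.393 and 0.576). The pairing there comes from the data and not from the labels. Deviations within a group of 3 cancel out, so a replicate 1 array that stands apart moves replicates 2 and 3 the other way. Pairs of different number can then correlate too, as 102S 2 µg replicate 2 did with MCC 2 µg replicate 3 (0.246). The rule therefore cannot tell pairing by number from replicate 1 standing apart, and the main fit used no pairing. Under either reading a deviation shared by same-numbered arrays stayed in the spread of the main fit. Genes that did not pass there may thus differ, and counts with the replicate number as a block are given below. Alternatives planned beforehand were no filter, a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, 1 probe set per gene, a fit of the compared groups alone, the replicate number as a block, and leaving out each array in turn. After the data had been seen, 4 more were added. These were a block for female-type against male-type sex-linked transcripts, the male-type arrays alone, the 3′ minus 5′ difference of the β-actin control probe sets as a covariate, and a fit without the 2 arrays in which that difference exceeded 2 log2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.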

Results

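The arrays profiled 5CC7 T cells taken from recipient mice 48 h after injection of a strong agonist peptide (MCC) or a weak agonist peptide (102S), each at 2 µg and at 0.2 µg, with 3 arrays per group. The design asks how the transcripts of responding cells differ with the strength of the peptide and with its dose. Replicates of a group correlated between r = 0.977 and 0.995 across probe sets.

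Sex-linked transcripts and RNA controls differed between arrays within groups. Xist, transcribed from the inactive X chromosome of female cells, lay between 10.35 and 11.03 log2 on the replicate 1 array of every group and between 2.27 and 2.78 on the 8 others. The Y-linked gene Eif2s3y lay between 3.31 and 4.26 on the same 4 arrays and between 8.75 and 9.37 on the others. Group means below the filter (log2 4.48) lay near this reading of an absent transcript, so differences from them were taken as lower limits, without folds, and interactions that include them as inexact. Replicate 1 was thus female-type and replicates 2 and 3 were male-type in all 4 groups. The 3′ minus 5′ difference of the β-actin control, which grows when RNA is degraded or incompletely copied, averaged 0.63 ± 0.12 log2 with 2 µg of MCC and 1.62 ± 0.81 with 0.2 µg of MCC (SD, n = 3). It averaged 1.24 ± 0.41 with 2 µg of 102S and 1.33 ± 0.88 with 0.2 µg of 102S. The first principal component held 41.8% of the variance and ordered the arrays by peptide and dose, and the second held 31.8%.

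**Figure D1:**
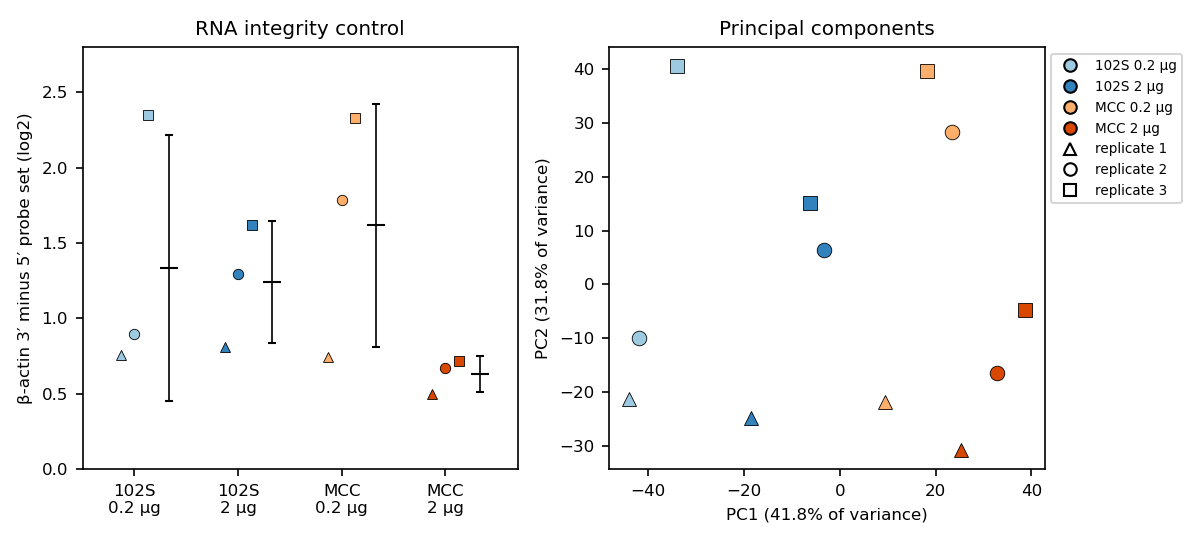
The left panel gives the β-actin 3′ minus 5′ difference (log2) of each array, with the mean and SD of each group of 3, and the right panel gives each array's first and second principal component (41.8% and 31.8% of the variance). The 4 replicate 1 arrays have low second components, between -30.7 and -21.2, and the arrays with the highest β-actin differences, 2.33 and 2.35, have the highest second components.

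At 2 µg, most mitosis genes and part of the DNA replication, activation and inhibitory receptor genes were higher in cells that had met MCC than in cells that had met 102S, and part of the naive-cell genes were lower. Of the lists called at this dose only the inhibitory receptors held with an estimated correlation. Nrp1, the neuropilin-1 co-receptor for semaphorins and VEGF, was 9.32-fold higher with MCC, at 9.36 ± 0.28 against 6.13 ± 0.30 log2 (SD, n = 3). Tiam1, an exchange factor for the GTPase Rac, was 7.64-fold higher, and Ccr6, the receptor for the chemokine CCL20, was higher by 2.88 ± 0.27 log2. Ccr9, a homing receptor for the gut, was lower with MCC, at 3.69 ± 0.40 against 6.78 ± 0.17 log2. The cytokine signalling inhibitor Socs3 (-2.97 ± 0.55 log2), the chemokine receptor Cxcr4 (-2.63 ± 0.35) and the IL-7 receptor chain Il7r (-2.21 ± 0.23) were lower as well.

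Other large increases with MCC at 2 µg were in the phospholipid scramblase Plscr1 (2.65 ± 0.28 log2), the cyclophilin Ppic (2.57 ± 0.31), the actin-capping protein Capg (2.53 ± 0.12), Endod1 (2.43 ± 0.21), the actin-binding synaptopodin gene Synpo (2.32 ± 0.29), Mdfic (2.20 ± 0.23) and the spindle checkpoint kinase Bub1 (2.15 ± 0.29). Their limma Benjamini-Hochberg adjusted p-values lay between 5.78e-07 and 0.000785. Large decreases were also seen in the NK receptor chain Klrd1 (-2.68 ± 0.34), Pdlim4 (-2.37 ± 0.31), the circadian repressor Nr1d2 (-2.12 ± 0.27), the death receptor family member Tnfrsf25 (-2.05 ± 0.20), the Rab exchange factor Dennd5a (-2.02 ± 0.22) and the noncoding RNA Lncpint (-2.00 ± 0.20). All 20 of these genes, chosen by size, stayed called whichever array was left out.

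By gene list at 2 µg, 23 of 25 measured mitosis genes were higher with MCC and 2 did not pass, with 24 higher when adjusted over the list alone. Kif11, a spindle motor, rose by 1.88 ± 0.19 log2 and the DNA topoisomerase Top2a by 1.77 ± 0.18. The mitosis list was called by camera (adjusted p = 7.05e-30; adjusted p = 0.0599 with an estimated correlation). Of 25 DNA replication genes, 13 were higher and 12 did not pass, with 20 higher when adjusted over the list alone, among them the DNA ligase Lig1 (1.17 ± 0.13) and the primase Prim1 (1.04 ± 0.15). Its camera call had adjusted p = 2.4e-14, and adjusted p = 0.0671 with an estimated correlation. Of 8 inhibitory receptors 5 were higher by either adjustment, including Pdcd1 (2.01 ± 0.14), Cd200 (1.70 ± 0.16), Cd160 (1.66 ± 0.30) and Ctla4 (1.32 ± 0.32). The call of Ctla4 was lost in 5 omissions of 1 array (highest adjusted p = 0.0873). This list held with both (adjusted p = 7.73e-07; adjusted p = 0.0147 with an estimated correlation). Among 19 genes of T cell receptor-induced activation, 8 were higher by either adjustment, for example the hyaluronan receptor Cd44 (1.34 ± 0.15) and the costimulatory receptor Tnfrsf4 (1.72 ± 0.19). Its adjusted p was 1.46e-06, and adjusted p = 0.0599 with an estimated correlation.

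Lists named for T cell subsets also held members that differed at 2 µg. Some of these genes stand in more than 1 list, such as Pdcd1 and Cd200 in the inhibitory receptor and follicular helper lists. Such genes are not further results. Of 12 regulatory T cell genes 6 were higher and 2 lower by either adjustment, led by Capg and Nrp1 (camera adjusted p = 5.24e-05; adjusted p = 0.065 with an estimated correlation). Foxp3, which defines that subset, lay below the intensity filter in all 4 groups, with means between 3.36 and 4.04 log2. Of 13 follicular helper (Tfh) genes 6 were higher over all genes, and 6 higher and 1 lower when adjusted over the list alone. Pdcd1, Cd200, Slamf6 (0.77 ± 0.11) and the coactivator Pou2af1 (0.70 ± 0.15) led it (adjusted p = 0.000748; adjusted p = 0.163 with an estimated correlation). In the Th17 list, 2 of 6 genes were higher by either adjustment, Ccr6 and the aryl hydrocarbon receptor Ahr (1.28 ± 0.31), and that list had camera adjusted p = 0.01 (adjusted p = 0.115 with an estimated correlation). Of 22 genes of naive and quiescent cells 9 were lower, and 11 when adjusted over the list alone, including Il7r, the chromatin organiser Satb1 (-0.95 ± 0.11) and the quiescence factor Klf2 (-1.56 ± 0.17). The naive list had adjusted p = 3.66e-05, and adjusted p = 0.404 with an estimated correlation. In the memory precursor and terminal effector list 3 of 6 genes were lower, Il7r, Cxcr4 and the transcriptional inhibitor Id2 (-0.66 ± 0.17). When adjusted over the list alone 4 were lower (camera adjusted p = 0.00204, and adjusted p = 0.189 with an estimated correlation). That list pools genes of both fates, so its direction does not stand for either. Markers of CD8 T and NK cells moved beside these groups: Klrd1 and the granzyme Gzma (-1.34 ± 0.35) were 2 of 5 measured that were lower by either adjustment (adjusted p = 0.0231; adjusted p = 0.126 with an estimated correlation). The B cell marker list was not called (adjusted p = 0.262), although Cd74, which chaperones class II molecules, was higher by 1.19 ± 0.22 log2.

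In all, 1392 of 13556 probe sets, for 1041 genes, differed between MCC and 102S at 2 µg (limma, Benjamini-Hochberg), with 548 higher and 844 lower with MCC, 224 and 200 of them by at least 2-fold. The β-actin 3′ minus 5′ difference moved with this contrast too, at 0.63 ± 0.12 with MCC and 1.24 ± 0.41 with 102S, and the groups did not overlap in it. With the arrays paired by replicate number as a block 2485 were called. With the sex type as a block 2059 were called, and 772 in the male-type arrays alone; the female-type arrays were 1 per group and gave no test. The β-actin difference as a covariate gave 3330 calls, and ended the call of the CD8 T and NK cell markers (adjusted p = 0.107, over the alternatives tested with camera 0.0111 to 0.126). Leaving out 102S 2 µg replicate 1, 2 or 3 gave 785, 888 or 700, and leaving out MCC 2 µg replicate 3 gave 917, of which 471 were higher and 446 lower.

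At 0.2 µg, most of the 10 highest differences among the genes named by size were in genes of dividing cells. Mki67, the marker of cycling cells, stood at 9.48 ± 0.19 log2 with MCC and 3.96 ± 0.19 with 102S (SD, n = 3), with adjusted p = 1.35e-07. Birc5, the survivin gene, stood at 8.38 and 3.38, and the cyclin Ccnb2 at 8.18 and 3.42. The ribonucleotide reductase subunit Rrm2 and the Wnt ligand Wnt10a were 25.4-fold higher each. Klf2 and Il7r, both genes of resting T cells, were 10.1-fold and 10.4-fold lower with MCC. Pdlim4 was lower by more still, at 5.62 ± 0.67 against 9.27 ± 0.20 log2.

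Further genes chosen by size at 0.2 µg were the spindle protein Nusap1 (4.54 ± 0.23 log2), the activation glycoprotein Cd83 (4.39 ± 0.20), the PCNA-binding factor Pclaf (4.36 ± 0.28), the ubiquitin-conjugating enzyme Ube2c (4.34 ± 0.30) and the kinetochore gene Nuf2 (3.82 ± 0.27). Lower with MCC were the kinase Sgk1 (-2.93 ± 0.41), Socs3 (-2.82 ± 0.55), the death ligand Fasl (-2.71 ± 0.25), the growth factor binding protein Igfbp4 (-2.48 ± 0.23), Klrd1 (-2.35 ± 0.34), the Rap exchange factor Rasgrp2 (-2.27 ± 0.29) and Cxcr4 (-2.16 ± 0.35). Adjusted p-values of the 20 named by size lay between 1.35e-07 and 0.00472, and all 20 stayed called whichever array was left out.

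**Figure D2:**
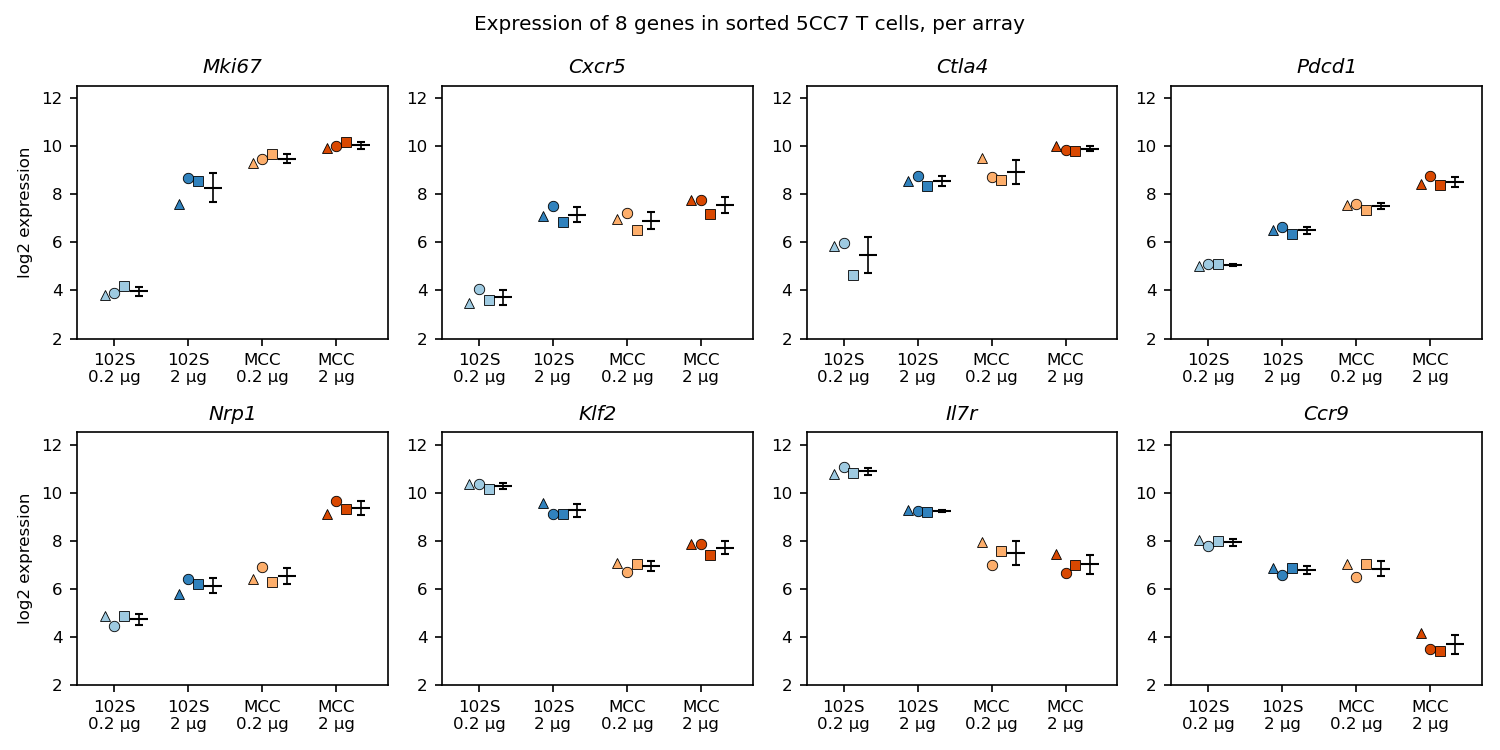
Log2 expression of 8 genes on each array, with the mean and SD of each group of 3 beside the points; triangles, circles and squares are replicates 1, 2 and 3. Mki67, Cxcr5 and Ctla4 are low with 0.2 µg of 102S, at group means of 3.96, 3.71 and 5.49, whereas Ccr9 is low with 2 µg of MCC, at 3.69.

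Of the mitosis list, 23 of 25 genes were higher with MCC at 0.2 µg and 24 when adjusted over the list alone, with a median difference of 2.53 log2 (camera adjusted p = 1.5e-31; adjusted p = 0.025 with an estimated correlation). Of 25 DNA replication genes 21 were higher, and 23 when adjusted over the list alone, including the thymidine kinase Tk1 (2.96 ± 0.27) and the polymerase Pole (1.98 ± 0.19). Their adjusted p was 6.78e-20, and adjusted p = 0.025 with an estimated correlation. Inhibitory receptors were higher for 5 of 8 by either adjustment, with Cd200 at 3.41 ± 0.16, Pdcd1 at 2.43 ± 0.14, Ctla4 at 3.45 ± 0.32 and Pdcd1lg2 at 2.39 ± 0.30 log2. Activation genes were higher for 11 of 19, and for 12 when adjusted over the list alone, for example Cd83, Cd44 (2.34 ± 0.15), Tnfrsf4 (2.82 ± 0.19) and Icos (1.65 ± 0.12). Of 12 regulatory T cell genes 10 were higher, and 11 when adjusted over the list alone, among them Capg (2.00 ± 0.12) and the TNF receptor family members Tnfrsf18 (1.63 ± 0.13) and Tnfrsf9 (2.35 ± 0.20). Of 13 Tfh genes 10 were higher and 1 lower by either adjustment, with the follicular homing receptor Cxcr5 at 3.19 ± 0.25. These 4 lists had adjusted p = 9.89e-06, 2.13e-11, 6.65e-12 and 1.02e-08 in that order. They held with adjusted p = 0.0112, 0.0112, 0.0112 and 0.025 with an estimated correlation.

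Oxidative phosphorylation genes were higher for 4 of 28 at 0.2 µg, and for 9 when adjusted over the list alone, among them Cox6c (0.58 ± 0.12) and Atp5c1 (0.37 ± 0.08), subunits of cytochrome oxidase and ATP synthase (adjusted p = 0.000664; adjusted p = 0.513 with an estimated correlation). Naive and quiescence genes were lower for 10 of 22, and for 12 when adjusted over the list alone (adjusted p = 1.83e-07; adjusted p = 0.296 with an estimated correlation). Of 5 CD8 T and NK cell markers 2 were lower by either adjustment, Klrd1 and the perforin gene Prf1 (-1.23 ± 0.22), with adjusted p = 0.00629, and adjusted p = 0.0642 with an estimated correlation. Among 5 B cell markers, Cd74 (1.38 ± 0.22) and Cd79b (1.26 ± 0.33) were higher and the immunoglobulin heavy chain Ighm (-0.98 ± 0.09) lower, by either adjustment, and that list was not called (adjusted p = 0.868).

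At 0.2 µg, 1939 probe sets for 1452 genes differed between the peptides (limma, Benjamini-Hochberg), 1064 higher and 875 lower with MCC, 404 and 155 of them by at least 2-fold. Median centring changed the split of 54.9% higher to 957 higher and 1188 lower, which is 44.6%. The split also turned with the sex type as a block, to 1441 higher and 1565 lower of 3006 calls, and without MCC 0.2 µg replicate 1 (1303 and 1482) or 102S 0.2 µg replicate 3 (1134 and 1332). There were 1487 calls in the male-type arrays alone. The covariate for the β-actin difference gave 3645 and a fit of the 6 arrays alone 1071; leaving out 102S 0.2 µg replicate 1 or 2 gave 1149 or 1147, and leaving out MCC 0.2 µg replicate 2 or 3 gave 1051 or 1241.

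Several genes of helper cells did not separate the peptides at 2 µg, the higher matched dose. Bcl6, the transcriptional repressor of Tfh cells, differed by -0.26 log2 (95% interval -0.56 to 0.04), Cxcr5 by 0.41 (-0.13 to 0.94), the Th2 regulator Gata3 by 0.23 (-0.07 to 0.52), the immediate early receptor Nr4a1 by 0.32 (-0.11 to 0.76), the growth regulator Myc by 0.15 (-0.57 to 0.87) and the IL-2 receptor chain Il2ra by 0.30 (-0.16 to 0.77). At 0.2 µg Bcl6 (0.98, 0.68 to 1.28), Nr4a1 (0.95, 0.52 to 1.38) and Il2ra (0.74, 0.28 to 1.20) were higher with MCC, while Myc (-0.46, -1.18 to 0.26), the inhibitory receptor Lag3 (0.14, -0.37 to 0.65) and Gata3 (-0.44, adjusted p = 0.0507) did not pass. A second tested probe set of Bcl6 showed no call at either dose. The call of Il2ra at 0.2 µg was lost without the filter (adjusted p = 0.0542; 0.0559 for its second probe set), in the 6 arrays alone (0.0846), in the male-type arrays alone (0.0757), without the 2 arrays of highest β-actin difference (0.0855) and in 4 omissions of 1 array (highest 0.148). That of Nr4a1 was lost in the 6 arrays alone (0.0623). Calls were gained by Bcl6 at 2 µg with the β-actin covariate (0.035) and by Myc at 0.2 µg without 102S 0.2 µg replicate 3 (0.0368). Gata3 at 0.2 µg was called in 7 alternatives and 2 omissions, among them the replicate number as a block (adjusted p = 0.00855). The activation factor Irf4 differed at both, by 1.22 (0.81 to 1.63) and 2.28 (1.87 to 2.69), and Lag3 at 2 µg, by 0.85 (0.34 to 1.36). The call of Lag3 was lost without the filter (adjusted p = 0.055) and in 5 omissions of 1 array (highest adjusted p = 0.117). Of 12164 probe sets not called at 2 µg, 10779 had a 95% interval within 1 log2 of no difference, as did 10172 of 11617 at 0.2 µg.

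Both doses shared many of the genes that differed between the peptides. Higher with MCC at both doses were 434 probe sets, where 43 were expected from independent lists. Lower at both were 415, where 54.5 were expected. Both comparisons used the same estimate of the spread per probe set, which raises overlaps in either direction, so these expected counts may be too low. In opposite directions 2 were called. Across probe sets, the peptide differences at the 2 doses correlated with r = 0.62 (jackknife SE 0.24 over arrays) and rho = 0.50; genes are not independent replicates, and this was 1 of 3 such correlations.

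Raising the dose of MCC from 0.2 to 2 µg changed fewer genes. Nrp1 was 7.03-fold higher at 2 µg, at 9.36 ± 0.28 against 6.54 ± 0.34 log2 (SD, n = 3), and Synpo 4.89-fold higher. Ccr9 was lower, at 3.69 ± 0.40 against 6.84 ± 0.32, as was Dennd5a (-2.08 ± 0.22 log2). Klf2, which fell with the dose of 102S, was higher at 2 µg of MCC by 0.756 log2. Its call was lost in 6 alternatives and in 4 omissions of 1 array. Mki67 did not pass, with a difference of 0.54 ± 0.24 log2 (adjusted p = 0.261; 0.0281 with the β-actin covariate). The β-actin 3′ minus 5′ difference moved with this contrast, from 1.62 ± 0.81 at 0.2 µg to 0.63 ± 0.12 at 2 µg.

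Also higher at 2 µg of MCC were Ppic (2.14 ± 0.31 log2), Ccr6 (1.90 ± 0.27), the nucleoside transporter Slc29a1 (1.90 ± 0.33), the endosome tether Eea1 (1.77 ± 0.35), Slc9b2 (1.73 ± 0.21), Mdfic (1.73 ± 0.23), the prostaglandin receptor Ptger2 (1.69 ± 0.24) and Spry1, an inhibitor of Ras signalling (1.60 ± 0.18). Lower were Iftap (-2.02 ± 0.20), the transcription factor Nfix (-1.71 ± 0.31), Pmepa1 (-1.67 ± 0.32), Klrd1 (-1.63 ± 0.34), the orphan receptor Gpr83 (-1.58 ± 0.24), Pdlim4 (-1.51 ± 0.31), the coactivator Ppargc1b (-1.46 ± 0.29) and the GTPase Rab6b (-1.46 ± 0.26). Of the 20 genes named by size, 12 stayed called whichever array was left out. Without MCC 0.2 µg replicate 3, the calls of Slc29a1, Eea1, Nfix, Pmepa1, Klrd1, Pdlim4, Ppargc1b and Rab6b were lost, and the highest adjusted p among them over all omissions was 0.169, for Pdlim4. Omitting MCC 2 µg replicate 2 also ended the calls of Slc29a1, Eea1, Pmepa1, Klrd1 and Pdlim4, and omitting MCC 0.2 µg replicate 2 those of Slc29a1, Eea1, Nfix, Pmepa1 and Ppargc1b. Slc29a1, Eea1 and Pdlim4 were also lost without MCC 2 µg replicate 1, and Eea1, Klrd1 and Pdlim4 without MCC 2 µg replicate 3.

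Among gene lists for the dose of MCC, 2 of 8 inhibitory receptors rose, Pdcd1 (1.02 ± 0.14 log2) and Cd200 (1.05 ± 0.16), with 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.000682; adjusted p = 0.103 with an estimated correlation). Of 25 mitosis genes 2 rose, the centromeric histone Cenpa (0.73 ± 0.15) and Kif11 (0.85 ± 0.19), and 12 when adjusted over the list alone (adjusted p = 2e-10; adjusted p = 0.353 with an estimated correlation). Of 13 Tfh genes 4 rose by either adjustment, Slamf6 (0.86 ± 0.11), Pdcd1, Cd200 and Pou2af1 (0.97 ± 0.15), with adjusted p = 5.09e-05, and adjusted p = 0.256 with an estimated correlation. Ribosome biogenesis genes fell for 3 of 25, Gnl3 (-1.001 ± 0.15), Nop56 (-0.92 ± 0.14) and Mybbp1a (-0.74 ± 0.12), all nucleolar proteins, and for 9 when adjusted over the list alone (adjusted p = 5.09e-05; adjusted p = 0.393 with an estimated correlation). Of 17 genes of the T cell receptor complex 0 passed by either adjustment, although camera called the list higher (adjusted p = 0.0168; adjusted p = 0.814 with an estimated correlation). With the β-actin difference as a covariate camera turned the T cell receptor complex list to the lower side (adjusted p = 0.997), and without the 2 arrays of highest β-actin difference it was not called (adjusted p = 0.0598). The range over the alternatives tested with camera was 0.0025 to 0.997.

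Between the doses of MCC 239 probe sets for 189 genes differed (limma, Benjamini-Hochberg), 96 higher and 143 lower at 2 µg, 47 and 50 of them by at least 2-fold. Which direction held the majority was not stable. With the arrays paired by replicate number as a block 1563 were called, 911 higher and 652 lower. The sex type as a block gave 889 (448 higher and 441 lower), the male-type arrays alone 591 (359 and 232), a fit without the 2 arrays of highest β-actin difference 97 (56 and 41) and the 6 arrays alone 74 (52 and 22). With the β-actin covariate 542 were called, 169 higher and 373 lower, 215 of the 239 among them. Leaving out MCC 2 µg replicates 1, 2 and 3 in turn gave 133, 121 and 135 (76 higher and 59 lower in the last), and MCC 0.2 µg replicates 1, 2 and 3 gave 1208 (679 and 529), 107 (54 and 53) and 61 (38 and 23).

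Raising the dose of 102S from 0.2 to 2 µg moved genes mostly upward, and genes of dividing cells were among the largest increases. Mki67 rose from 3.96 ± 0.19 to 8.28 ± 0.59 log2 (SD, n = 3), a difference of 4.32 ± 0.24, Birc5 from 3.38 to 7.38 and Ccnb2 from 3.42 to 7.20. Cxcr5 rose from 3.71 ± 0.30 to 7.15 ± 0.32, and Ctla4 8.40-fold. Pdlim4 fell 6.87-fold, and Dntt, the template-independent polymerase of antigen receptor joining, fell 4.13-fold.

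Ube2c (3.44 ± 0.30 log2), Nusap1 (3.36 ± 0.23), Rrm2 (3.31 ± 0.30), Pclaf (3.22 ± 0.28) and Cd83 (2.81 ± 0.20) also rose with the dose of 102S. Falls were seen in Igfbp4 (-1.66 ± 0.23), Il7r (-1.64 ± 0.23), the myosin Myo6 (-1.57 ± 0.24), Ncmap (-1.18 ± 0.17), Ccr9 (-1.15 ± 0.21), Adgrg3 (-1.05 ± 0.22), the amino acid transporter Slc7a5 (-1.04 ± 0.16) and Klf2 (-1.01 ± 0.17). Adjusted p-values of the 20 genes lay between 2.49e-06 and 0.0211, and 18 stayed called whichever array was left out. The call of Ccr9 was lost without 102S 2 µg replicate 2 (adjusted p = 0.0711), and that of Adgrg3 in 4 of the omissions, with a highest adjusted p of 0.13. Adgrg3 was not called without 102S 2 µg replicate 1 or 2, or without 102S 0.2 µg replicate 1 or 2.

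By list, 21 of 25 mitosis genes rose with the dose of 102S, and 22 when adjusted over the list alone, with a median of 1.51 log2 (adjusted p = 2.48e-36; adjusted p = 0.0144 with an estimated correlation). DNA replication genes rose for 5 of 25, including Rrm2, Tk1 (1.92 ± 0.27), the licensing factor Cdc6 (1.70 ± 0.32) and Rfc4 (0.68 ± 0.15), and 15 were higher and 1 lower when adjusted over the list alone (adjusted p = 1e-08; adjusted p = 0.143 with an estimated correlation). Of 13 Tfh genes 9 rose by either adjustment, among them Cxcr5, Cd200 (2.76 ± 0.16), Slamf6 (1.07 ± 0.11) and Bcl6 (1.17 ± 0.14). Regulatory T cell genes rose for 7 of 12, and 9 when adjusted over the list alone, with Ctla4, the folate receptor family member Izumo1r (1.33 ± 0.17), the Ikaros family factor Ikzf4 (1.53 ± 0.20) and Tnfrsf18 (0.89 ± 0.13). Inhibitory receptors rose for 4 of 8, and 5 when adjusted over the list alone, and activation genes for 8 of 19, and 11 when adjusted over the list alone. For these 4 lists adjusted p was 1.67e-15, 2.67e-11, 8.81e-06 and 2.4e-10 in that order. They held with adjusted p = 0.0108, 0.0108, 0.0108 and 0.0116 with an estimated correlation.

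Ribosome biogenesis genes fell for 4 of 25 with the dose of 102S, Mybbp1a (-0.60 ± 0.12 log2), Gar1 (-0.55 ± 0.13), Gnl3 (-0.62 ± 0.15) and Wdr43 (-0.56 ± 0.14), and for 10 when adjusted over the list alone (adjusted p = 2.4e-10; adjusted p = 0.0671 with an estimated correlation). Naive and quiescence genes fell for 4 of 22, Pdlim4, Igfbp4, Il7r and Klf2, with 4 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00305; adjusted p = 0.616 with an estimated correlation). In the CD8 T and NK cell markers Prf1 fell (-0.93 ± 0.22), 1 of 5, and 2 fell when adjusted over the list alone (adjusted p = 0.00443; adjusted p = 0.0642 with an estimated correlation). Of 14 apoptosis genes 2 rose, the BH3 protein gene Bcl2l11 (0.68 ± 0.14) and the death receptor Fas (0.62 ± 0.14), and 3 when adjusted over the list alone (adjusted p = 0.0241; adjusted p = 0.536 with an estimated correlation). Of 17 genes of the T cell receptor complex 2 rose, the receptor-associated glycoproteins Cd5 (1.27 ± 0.14) and Cd6 (1.06 ± 0.21), and 4 when adjusted over the list alone (adjusted p = 0.0336; adjusted p = 0.618 with an estimated correlation). Apoptosis genes were not called in the male-type arrays alone (adjusted p = 0.0967) or without the 2 arrays of highest β-actin difference (adjusted p = 0.241), and over the alternatives tested with camera adjusted p lay between 0.0182 and 0.536. Without the same 2 arrays the T cell receptor complex had adjusted p = 0.44, in a range of 0.011 to 0.618.

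Between the doses of 102S 429 probe sets for 333 genes differed (limma, Benjamini-Hochberg), 360 higher and 69 lower at 2 µg, 189 and 20 of them by at least 2-fold. The sex type as a block gave 662 calls, and the male-type arrays alone 269. With the β-actin covariate 1420 were called. Leaving out 102S 2 µg replicate 2 or 3 gave 210 or 234, and leaving out 102S 0.2 µg replicate 1 or 2 gave 279 or 264. Higher with dose for both peptides were 41 probe sets (2.55 expected from independent lists) and lower for both 22 (0.728 expected). These expected counts may be too low as well, because of the shared estimate of the spread. In opposite directions 2 were called higher and 5 lower with the dose of MCC. Across probe sets the dose effects of MCC and 102S correlated with r = 0.27 (jackknife SE 0.39) and rho = 0.25. Without 102S 0.2 µg replicate 3 the value was r = -0.00792, and without another array it lay between 0.102 (102S 2 µg replicate 1) and 0.406 (102S 0.2 µg replicate 1).

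The peptide difference itself changed with dose for a group of genes, and for most of them it was larger at 0.2 µg. Mki67 differed between the peptides by 1.75 ± 0.24 log2 at 2 µg and 5.53 ± 0.24 at 0.2 µg, an interaction of -3.78 ± 0.34 (limma adjusted p = 0.000294). For Cxcr5 the differences were 0.41 ± 0.25 and 3.19 ± 0.25 (interaction -2.78 ± 0.35), and for Bcl6 -0.26 ± 0.14 and 0.98 ± 0.14 (interaction -1.23 ± 0.20, not called in the male-type arrays alone, adjusted p = 0.0989). Klf2 was lower with MCC by -1.56 ± 0.17 at 2 µg and -3.33 ± 0.17 at 0.2 µg, an interaction of 1.77 ± 0.24. Ccr6 went the other way, with a difference of 2.88 ± 0.27 at 2 µg and 0.88 ± 0.27 at 0.2 µg (interaction 2.00 ± 0.38).

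Other genes with a larger difference at 0.2 µg were Birc5 (interaction -3.72 ± 0.45 log2), Rrm2 (-3.47 ± 0.42), the organic cation transporter Slc22a2 (-3.38 ± 0.26), Wnt10a (-3.13 ± 0.35), Cd83 (-3.05 ± 0.28), Ccnb2 (-2.97 ± 0.44), Nusap1 (-2.82 ± 0.32) and Pclaf (-2.73 ± 0.40). Positive interactions were found for the IL-18 receptor chain Il18r1 (2.21 ± 0.21), Spry1 (1.47 ± 0.26) and Ighm (0.71 ± 0.13). Il18r1 was lower with MCC at 0.2 µg (6.68 ± 0.17 against 8.61 ± 0.12 log2, SD, n = 3) and stood at 7.99 ± 0.18 and 7.71 ± 0.21 at 2 µg. Of these 15 genes, 12 stayed called whichever array was left out. The exceptions were Ccr6, called in all but 7 omissions (highest adjusted p = 0.109), Spry1, in all but 6 (0.0711), and Ighm, in all but 7 (0.0981). Leaving out 102S 2 µg replicate 3, 102S 0.2 µg replicate 1 or 2, or MCC 2 µg replicate 2, ended the calls of all 3 of these genes.

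**Figure D3:**
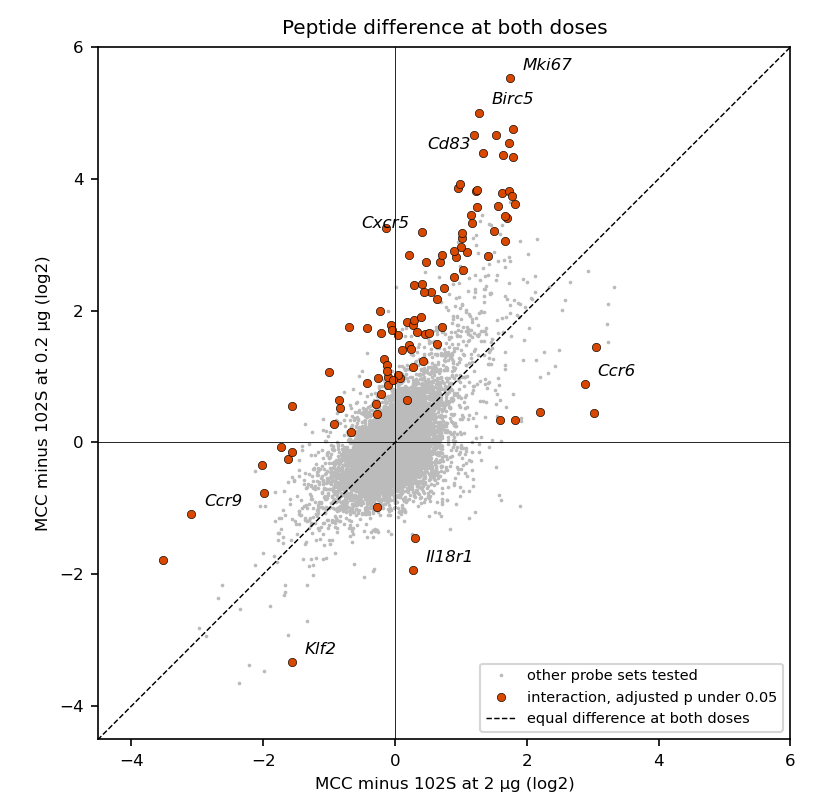
Each point is a probe set, with the MCC minus 102S difference at 2 µg on the x axis and at 0.2 µg on the y axis (log2); the 104 with an interaction are drawn in orange and the dashed line marks equal differences. Mki67 lies at 1.75 and 5.53, above the line, and Ccr6 at 2.88 and 0.88, below it.

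Of 25 mitosis genes 8 had a negative interaction, and 15 when adjusted over the list alone, with a median of -0.99 log2 (camera adjusted p = 1.2e-15; adjusted p = 0.158 with an estimated correlation). Of 25 DNA replication genes 2 did, Rrm2 and Tk1 (-1.96 ± 0.38), and 10 when adjusted over the list alone (adjusted p = 5.31e-09; adjusted p = 0.193 with an estimated correlation). Activation genes had negative interactions for 4 of 19, Cd83, Tnfrsf18 (-1.59 ± 0.18), Icos (-1.20 ± 0.17) and Tnfrsf9 (-1.61 ± 0.28), and for 8 when adjusted over the list alone (adjusted p = 6.99e-08; adjusted p = 0.1 with an estimated correlation). Tfh genes did for 5 of 13, including Cxcr5, Cd200 (-1.71 ± 0.23), Icos and Bcl6, and for 6 when adjusted over the list alone (adjusted p = 9.19e-06; adjusted p = 0.149 with an estimated correlation). Of 12 regulatory T cell genes 4 did, Ikzf4 (-2.44 ± 0.28), Gpr83 (-2.08 ± 0.34), Tnfrsf18 and Tnfrsf9, and 6 were negative and 2 positive when adjusted over the list alone (adjusted p = 0.000146; adjusted p = 0.149 with an estimated correlation). In the naive and quiescence list Klf2 had a positive interaction, 1 of 22, and 2 when adjusted over the list alone (adjusted p = 0.00224; adjusted p = 0.618 with an estimated correlation). The β-actin covariate ended that call (adjusted p = 0.516, over the alternatives tested with camera 0.000138 to 0.618). Naive and quiescence genes other than Klf2 did not pass. Of 8 inhibitory receptors 2 had a negative interaction, and 3 when adjusted over the list alone. Camera did not call that list (adjusted p = 0.137, and adjusted p = 0.324 with an estimated correlation). Among the inhibitory receptors Ctla4 had an interaction of -2.12 ± 0.45 that did not pass (adjusted p = 0.0598). It was called in 6 alternatives and 2 omissions of 1 array, among them the replicate number as a block (adjusted p = 0.00434). Pdcd1 had an interaction of -0.42 ± 0.20 (adjusted p = 0.581).

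An interaction was called for 104 probe sets of 87 genes (limma, Benjamini-Hochberg), 10 positive and 94 negative, 9 and 82 by at least 2-fold. The peptide difference was larger in size at 0.2 µg for 86 of them, 91 were also called at 0.2 µg and 59 at 2 µg, and for 26 the differences had opposite signs. With the sex type as a block 245 were called, in the male-type arrays alone 106, and with the β-actin covariate 285. Leaving out 102S 2 µg replicate 2 or 3 gave 63 or 66, 102S 0.2 µg replicate 1 gave 69, MCC 2 µg replicate 3 gave 68, and MCC 0.2 µg replicate 2 or 3 gave 62 or 67.

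Set beside 2 µg of 102S, 0.2 µg of MCC gave fewer called genes than the peptides did at either matched dose; the doses differ, so the values are given side by side only. The antiviral membrane protein gene Ifitm2 stood at 6.92 ± 0.59 log2 with 0.2 µg of MCC and 3.82 ± 0.22 with 2 µg of 102S (SD, n = 3). Wnt10a was 6.38-fold and the costimulatory receptor Tnfrsf4 4.84-fold higher with 0.2 µg of MCC. Fasl was lower by -2.48 ± 0.25 log2, Klf2 4.99-fold lower and Cxcr4 4.73-fold lower. Irf4 was higher by 0.82 log2 (95% interval 0.40 to 1.23), a call lost in 5 alternatives and in 6 omissions of 1 array. Cxcr5 stood at 6.90 ± 0.37 and 7.15 ± 0.32, a difference of -0.25 (95% interval -0.79 to 0.29), and Ctla4 differed by 0.38 (-0.32 to 1.08), neither of which passed, although Ctla4 did with the β-actin covariate (adjusted p = 0.00935).

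Further genes higher with 0.2 µg of MCC than with 2 µg of 102S were the phospholipase Pla2g4f (2.07 ± 0.21 log2), Marcksl1 (2.06 ± 0.37), Tiam1 (1.96 ± 0.15), the fatty acid binding protein Fabp5 (1.93 ± 0.18), the checkpoint kinase Chek1 (1.88 ± 0.24), the antithrombin gene Serpinc1 (1.68 ± 0.32) and Plscr1 (1.67 ± 0.28). Lower were Rasgrp2 (-1.84 ± 0.29), Il7r (-1.73 ± 0.23), Cdc42ep3 (-1.47 ± 0.26), the pseudokinase Trib2 (-1.46 ± 0.14), Lncpint (-1.45 ± 0.20), Art4 (-1.43 ± 0.26) and Rflnb (-1.35 ± 0.19). Of the 20 named by size 15 stayed called whichever array was left out. Without MCC 0.2 µg replicate 2, Marcksl1, Serpinc1, Plscr1, Cdc42ep3 and Art4 were no longer called, and the same 5 were lost without 102S 2 µg replicate 1 (highest adjusted p over the omissions 0.0925, for Serpinc1). Without 102S 2 µg replicate 2 Serpinc1 and Art4 were lost, without 102S 2 µg replicate 3 Art4, and without MCC 0.2 µg replicate 3 Marcksl1 and Art4.

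In this comparison 13 of 25 DNA replication genes were higher with 0.2 µg of MCC, and 23 when adjusted over the list alone (adjusted p = 2.8e-24; adjusted p = 0.0264 with an estimated correlation), for example Lig1 (1.03 ± 0.13 log2) and Pole (1.35 ± 0.19). Of 25 mitosis genes 13 were higher, and 20 when adjusted over the list alone, with Mki67 at 1.21 ± 0.24 (adjusted p = 3.25e-22; adjusted p = 0.0535 with an estimated correlation). Mki67 itself was not called in the 6 arrays alone (adjusted p = 0.101), without the 2 arrays of highest β-actin difference (0.067) or without MCC 0.2 µg replicate 2 or 3. Activation genes were higher for 8 of 19 by either adjustment, regulatory T cell genes for 3 of 12 (5 when adjusted over the list alone), and inhibitory receptors for 1 of 8, Pdcd1 at 0.99 ± 0.14 (3 when adjusted over the list alone; Pdcd1 was not called in the male-type arrays alone, adjusted p = 0.0688). Camera gave them adjusted p = 6.86e-08, 1.6e-07 and 0.000417, and for each adjusted p = 0.0264 with an estimated correlation. Ahr (1.501 ± 0.31) was the 1 of 6 Th17 genes that was higher, with 2 when adjusted over the list alone (adjusted p = 0.00141; adjusted p = 0.0535 with an estimated correlation). Camera also called oxidative phosphorylation higher, with 0 of 28 genes passing by either adjustment (adjusted p = 0.00034; adjusted p = 0.313 with an estimated correlation). Ribosome biogenesis was called higher with 0 of 25 genes passing, and 4 when adjusted over the list alone (adjusted p = 0.000684; adjusted p = 0.294 with an estimated correlation). Lower were 4 of 22 naive and quiescence genes, including the actin crosslinker Actn1 (-0.72 ± 0.11), and 11 when adjusted over the list alone (adjusted p = 7.77e-09; adjusted p = 0.207 with an estimated correlation). In the memory precursor and terminal effector list Il7r and Cxcr4 were lower, 2 of 6, and 3 when adjusted over the list alone. Camera gave that list adjusted p = 0.00114, and adjusted p = 0.207 with an estimated correlation. Migration and homing genes were lower for 4 of 15 and higher for 1, Cd44 (1.11 ± 0.15), with 5 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0143; adjusted p = 0.442 with an estimated correlation). Migration and homing genes were not called with the β-actin covariate (adjusted p = 0.0799) or without the 2 arrays of highest β-actin difference (adjusted p = 0.0507), in a range of 0.002 to 0.442 over the alternatives tested with camera.

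Between 0.2 µg of MCC and 2 µg of 102S 336 probe sets for 269 genes differed (limma, Benjamini-Hochberg), 212 higher and 124 lower with MCC, 95 and 19 of them by at least 2-fold. Median centring changed the split of 63.1% higher to 196 higher and 187 lower, which is 51.2%. With the arrays paired by replicate number as a block 1147 were called, 483 higher and 664 lower. The sex type as a block gave 874 calls (418 higher and 456 lower), the male-type arrays alone 130, the β-actin covariate 1176, a fit without the 2 arrays of highest β-actin difference 224, and the 6 arrays alone 150. Leaving out 102S 2 µg replicates 1, 2 and 3 gave 85, 157 and 176, and MCC 0.2 µg replicates 1, 2 and 3 gave 654 (289 higher and 365 lower), 93 and 117.

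**Figure D4:**
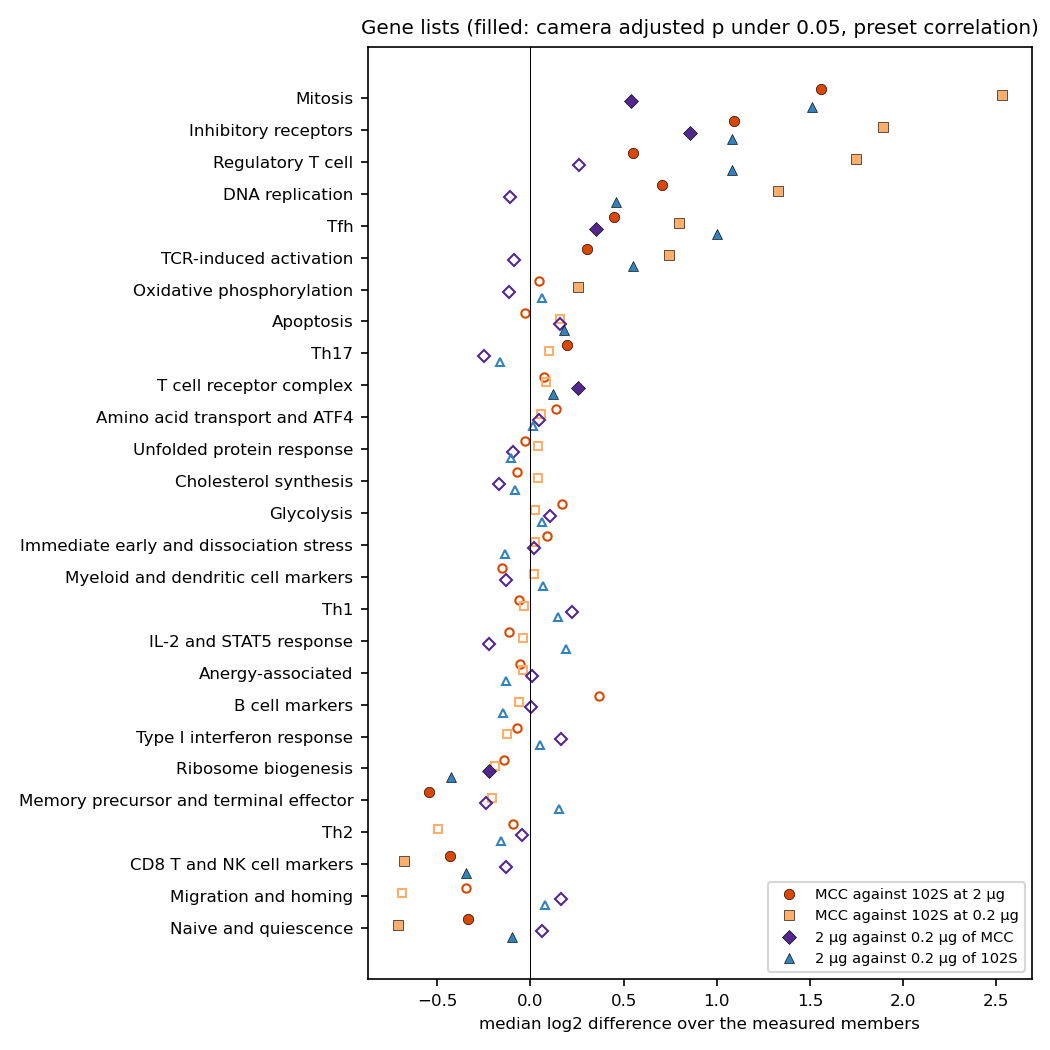
Median log2 difference over the measured genes of each list in the 4 comparisons at matched dose or matched peptide, with filled symbols where camera at the preset correlation gave an adjusted p under 0.05. Mitosis genes have medians of 1.56, 2.53, 0.54 and 1.51, and naive and quiescence genes have medians of -0.34 and -0.71 between the peptides.

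Of 2557 probe sets called in any of the 5 pairwise comparisons, 28.4% rose in group mean from 2 µg of MCC through 0.2 µg of MCC and 2 µg of 102S to 0.2 µg of 102S, as Il7r did (7.03 ± 0.39, 7.50 ± 0.50, 9.24 ± 0.05 and 10.9 ± 0.16 log2, SD, n = 3). The reverse order, as in Pdcd1 (8.51 ± 0.20, 7.50 ± 0.13, 6.503 ± 0.15 and 5.06 ± 0.03), was held by 23.7%. These probe sets were chosen for a difference between groups, mostly between the peptides, which favours such orders, so no share expected by chance is given. The peptide effect averaged over doses was called for 3108 probe sets and the dose effect averaged over peptides for 841. Across probe sets these averaged effects correlated with r = 0.64 (jackknife SE 0.27) and rho = 0.47. Without MCC 0.2 µg replicate 1 the value was r = 0.399. The β-actin difference was lowest with 2 µg of MCC (0.63), the group at the high end of both effects. A trend with RNA quality can therefore add to this correlation.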

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

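Of the tests in this part, those of the array's signal range, of RNA quality for the mitosis genes and for replicate 1, and of the sex type were chosen only after the result was seen. The test of RNA quality for the genes that moved with the dose of MCC, and the splits of the arrays into other groups, were written down before their results.

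The difference between MCC and 102S itself differed between the doses for 104 probe sets, and the genes with the largest such change were singled out for that difference between groups. More negative values, where MCC exceeded 102S more at 0.2 µg, were -3.78 log2 for Mki67, -3.72 for Birc5, -3.47 for Rrm2, -3.38 for Slc22a2, -3.13 for Wnt10a, -3.05 for Cd83, -2.97 for Ccnb2, -2.82 for Nusap1, -2.78 for Cxcr5 and -2.73 for Pclaf. Positive values were 2.21 for Il18r1, 2.00 for Ccr6, 1.77 for Klf2, 1.47 for Spry1 and 0.71 for Ighm. Mki67, Birc5, Rrm2, Ccnb2, Nusap1 and Pclaf serve DNA synthesis or cell division. Their values were low with 0.2 µg of 102S, at 3.96 log2 for Mki67 and 3.38 for Birc5, and higher in the 3 other groups. Means below the filter (log2 4.48) make the size of these interactions inexact.

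A signal ceiling could shrink the mitosis genes' difference at 2 µg if their highest values neared the top of the arrays' range. Their highest group means had a median of 7.15 log2, which lay 5.14 log2 below the 99th percentile of the arrays (12.29). Mki67 reached 10.03 log2 with 2 µg of MCC. This argues against a ceiling at the top of the arrays' range only. Single probe sets can saturate below that range, which was not tested. RNA degradation could enter because the β-actin 3′ minus 5′ difference varied within groups. With that difference as a covariate, which raised the interaction calls from 104 to 285, the median interaction of the 25 mitosis genes was -0.895, and between -1.09 and -0.798 with any 1 array left out, against -0.99 without the covariate. Of the 25, 10 were called, against 8 without it. This argues against a trend with the β-actin difference as the whole cause. In the replicate 1 arrays alone, where that difference ran from 0.499 to 0.809, the median was -0.80, but with 1 array per group this has no replicate spread and decides nothing. Which change in the cells may lie behind the larger difference at 0.2 µg stays open as well. With 0.2 µg of 102S the values may reflect fewer cells in division at 48 h, a lower level in each cell or a different time course. No unstimulated cells, cell counts or other time points were used here to separate these.

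Genes that differed between 2 µg and 0.2 µg of MCC did so beside a change in RNA quality, since β-actin 3′ minus 5′ averaged 0.63 with 2 µg and 1.62 with 0.2 µg. The replicate 1 arrays differed less, at 0.499 and 0.742. Of the 200 probe sets with the smallest p in replicates 2 and 3, 195 went the same way in replicate 1, which is 97.5%, where 63% of all probe sets did. The size of the replicate 1 difference was a median 0.479 of that in the others (quartiles 0.272 and 0.737), short of the 0.5 set beforehand. Choosing by small p inflates the size in the arrays used for the choice, so a ratio under 1 is expected without any degradation, and this one decides nothing. Whether RNA degradation adds to these differences stays open. With the β-actin difference as a covariate 215 of the 239 probe sets were still called. The sex type of the cells was balanced over the groups, so as a block it could not move these differences. That all 239 of the 239 stayed called says nothing about it, and whether the sexes respond differently to the dose was not tested.

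The replicate 1 arrays stood apart from replicates 2 and 3 in all 4 groups. Besides Xist (8.11 log2 higher) and the Y-linked Eif2s3y (-5.18) and Kdm5d (-4.75), the antiproliferative gene Btg2 was 2.13 higher, and 1747 probe sets were called in a fit with the 4 groups. RNA degradation could produce such a structure, because these arrays had low β-actin differences. Replicates 3 and 2 of 0.2 µg of 102S were of 1 sex type and had β-actin differences of 2.35 and 0.896. Across probe sets, their difference correlated with the replicate 1 difference in the 3 other groups at r = -0.666 (rho = -0.749). Genes are not independent replicates. Degradation needs this negative sign, but anything shared by the replicate 3 arrays enters the 2 differences with opposite signs and gives it too. Deviations of replicate 3 arrays from their group means correlated between 0.217 and 0.656 across groups. The correlation therefore cannot tell degradation from another source shared by the replicate 3 arrays. Of the 1602 called probe sets with a known chromosome, 46 lay on X or Y, which is 2.87%, against 2.95% of all tested. The sex of the donor cells and a different donor pool cannot be told apart, because both go with the replicate number. RNA quality goes with it only in part, since the male-type arrays with 2 µg of MCC had β-actin differences as low as replicate 1 arrays. The pattern may hold more than 1 source.

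Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For MCC against 102S at 2 µg, 1 of the 10, the real one, gave as many as 1392 calls, and the highest other gave 0. The real split was likewise the 1 of 10 with as many calls for the dose of MCC (239, highest other 0), the dose of 102S (429, highest other 0) and 0.2 µg of MCC against 2 µg of 102S (336, highest other 0). In the 3 of these comparisons that met the rule for pairing, the real split parts all 3 same-numbered pairs. The other splits that part all 3 pairs gave 0 calls, as did those that part 1. For MCC against 102S at 0.2 µg, 2 of the 10 gave as many as the real 1939. The other gave 3384 and set both replicate 1 arrays and 102S replicate 2 against the rest. Those 3 arrays had the lowest β-actin differences of the 6, so this split points to a structure of the samples; the count with the sex type as a block was 3006 and with the β-actin difference as a covariate 3645. For the interaction, with additive peptide and dose effects removed, 4 of 100 splits gave as many as the real 227, and the highest other gave 4973. The 3 larger splits, with 4973, 2765 and 1729 calls, all put the 4 replicate 1 arrays on 1 side. The arrays added to these 4 had β-actin differences between 0.67 and 1.30. Other splits with the same 4 arrays on 1 side gave 0 calls, and each added an array with a difference of at least 1.618. Replicate 1 alone thus does not set the larger splits apart, and they again point to a structure of the samples. With the sex type as a block the interaction was called for 245 probe sets, and with the β-actin covariate for 285.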

How the results depend on the processing

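The sex-type block, the male-type arrays alone, the β-actin covariate and the omission of the 2 arrays of highest β-actin difference were chosen after seeing the data; the other alternatives were planned. Counts below are called probe sets for MCC against 102S at 2 µg (1392), at 0.2 µg (1939), the dose of MCC (239), the dose of 102S (429), the interaction (104) and 0.2 µg of MCC against 2 µg of 102S (336), in this order. No filter, a filter at the 60th percentile, quantile normalization, median centring, no intensity trend and 1 probe set per gene left all 6 within 1.5 times these values. No called probe set changed sign under any alternative. With other filters, no intensity trend, 1 probe set per gene, the compared groups alone or a balanced block the differences stay the same, so no sign could turn. Only the other normalizations, the β-actin covariate and the fits with arrays left out could show a turn. A pseudocount was not run, because the values were log2 as deposited.

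The replicate number as a block gave 2485, 3496, 1563, 828, 321 and 1147, and it ended no call of a probe set or list. At 0.2 µg it turned the split of 1064 higher and 875 lower to 1578 and 1918. Correlations met the rule for pairing at 2 µg, for the dose of MCC and in the last comparison, where no list changed its call. In the others 1 same-numbered pair correlated below 0 (-0.287 at 0.2 µg and -0.0637 for the dose of 102S), so the rule was not met there, and not every array correlated best with its own number. The sex type as a block gave 3006, 889, 662, 245 and 874 for the results other than the first, which stayed within 1.5 times. In the male-type arrays alone the counts at 2 µg, for both doses and for the last comparison were 772, 591, 269 and 130. The β-actin covariate gave 3330, 3645, 542, 1420, 285 and 1176. Without the 2 arrays of highest β-actin difference the dose of MCC gave 97. With only the compared groups fitted, 0.2 µg gave 1071, the dose of MCC 74 and the last comparison 150. Fewer arrays estimate the spread in such a fit, but the same setting gave 1652 at 2 µg. For these and the other shifts the cause was not tested.

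Leaving out 1 array at a time gave between 700 and 1076, 1051 and 2785, 61 and 1208, 210 and 387, 62 and 142, and 85 and 654. Most omissions lowered the counts, and whether this came from the fewer arrays was not tested. The highest counts at 0.2 µg, for the dose of MCC, the interaction and the last comparison came without MCC 0.2 µg replicate 1. The correlation of peptide and dose effects ranged from 0.399 to 0.714, that of the peptide effects at both doses from 0.473 to 0.689. That of the dose effects of MCC and 102S ranged from -0.00792, a reversed sign without 102S 0.2 µg replicate 3, to 0.406.

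Camera called 10, 9, 5, 11, 6 and 11 lists at the preset correlation. With the correlation estimated per list it called 1, 6, 0, 5, 0 and 4, and fry called 13, 13, 5, 8, 7 and 9. The β-actin covariate raised the lists called for the interaction to 10. For named genes 12507 pairs of gene and alternative kept their side of the threshold, 457 gained a call, 708 lost it and 0 reversed. Signal limited the tests to probe sets with a mean above log2 4.48.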

Other observations

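The lists and key genes of this part were fixed beforehand, and the counts of signs and the values of lists on single arrays were chosen only after the results were seen.

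Il2 and Prdm1 had mean signals below the intensity filter and were tested only in the fit without it. Il2, the gene of the T cell growth factor, stood at 5.91 ± 0.50 and 4.46 ± 0.21 log2 with 2 and 0.2 µg of MCC, and at 4.12 ± 0.28 and 3.32 ± 0.22 with 2 and 0.2 µg of 102S (SD, n = 3). It was higher with MCC by 1.78 log2 at 2 µg (adjusted p = 0.000697), and with the dose of MCC by 1.45 (adjusted p = 0.0121), both lower limits. Differences between 2 means below the filter level (log2 4.48) are not given for these genes. Prdm1, which encodes the repressor Blimp-1, stood at 3.32, 3.77, 4.17 and 5.22 log2 in the same order of groups. It was lower with MCC at 0.2 µg by -1.45 (adjusted p = 0.000573), and lower with the dose of 102S by -1.05 (adjusted p = 0.0191). Tbx21, Ifng, Gzmb, Foxp3 and Il21 also lay below the filter and were not called without it.

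Among the 27 lists tested, 12 were called by camera in none of the 6 comparisons, and several had members that moved in different directions. The lowest adjusted p among these lists and comparisons was 0.0509, for the Th1 list with the dose of MCC. The values that follow are for MCC against 102S at 0.2 µg. In the interferon list, of 24 genes measured, 3 rose and 3 fell with MCC at 0.2 µg by either adjustment (adjusted p = 0.564), and the lowest adjusted p over the comparisons was 0.0872. Of 15 genes of the IL-2 and STAT5 response 5 rose and 2 fell at 0.2 µg (adjusted p = 0.288), and when adjusted over the list alone 6 rose and 2 fell. The receptor chain Il2rb was higher with MCC there by 2.62 ± 0.19 log2, and Socs3 lower. The Th1 list held 2 genes higher and 2 lower of 12 at 0.2 µg, with 3 higher and 4 lower when adjusted over the list alone (adjusted p = 0.739), among them the chemokine receptor Cxcr6 (2.13 ± 0.37) and Il18r1 (-1.93 ± 0.15). The Th2 list had 1 gene higher and 2 lower of 6, with 1 higher and 3 lower when adjusted over the list alone (adjusted p = 0.265). In the anergy list 4 rose and 3 fell of 14 by either adjustment (adjusted p = 0.868).

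In glycolysis 3 of 15 genes rose at 0.2 µg by either adjustment, with Pgk1 at 0.78 ± 0.09 log2 (adjusted p = 0.441 for the list). Of 17 genes of amino acid transport and the ATF4 response 2 rose and 1 fell by either adjustment (adjusted p = 0.564), and of 18 genes of cholesterol synthesis 1 rose, and 0 when adjusted over the list alone (adjusted p = 0.441). Of 20 genes of the unfolded protein response 2 fell, and 1 when adjusted over the list alone (adjusted p = 0.798). Immediate early genes, which also respond to tissue dissociation, had 2 higher and 2 lower of 13 by either adjustment, led by Dusp1 (1.41 ± 0.24) and Zfp36 (-1.30 ± 0.23), with adjusted p = 0.868. Of 6 markers of myeloid and dendritic cells 1 rose by either adjustment, the protease gene Ctss (0.40 ± 0.08), which other cells express too (adjusted p = 0.739). The B cell markers are given with the peptide comparisons, and their lowest adjusted p over the comparisons was 0.162. Erythroid markers had 1 measured gene, stromal and endothelial markers 3, sex-linked genes 4 and neutrophil markers 0, so these lists were not tested.

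For the 52 pairs of list and comparison that camera called, the median, the mean and the direction of the test had the same sign in all 52. Of the 110 pairs not called, 32 differed in sign. Ighm, at 10.47 log2 with 0.2 µg of MCC and 11.45 with 0.2 µg of 102S, was the B cell gene with an interaction, while Cd74, at 7.23, 7.23, 6.04 and 5.84 with 2 and 0.2 µg of MCC and 2 and 0.2 µg of 102S, followed the peptide.

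Among the CD8 T and NK cell markers, the median deviation from the mean over all arrays was 0.632, 0.717 and 0.70 in the 3 arrays with 0.2 µg of 102S and -0.562, -0.672 and -0.132 in those with 2 µg of MCC. For mitosis genes these deviations were -1.95, -1.81 and -1.70 against 1.28, 1.62 and 1.26.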
